A study of Saccharomyces cerevisiae with 27 samples.

How the data were processed

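Gene-level expected counts of 27 libraries were analysed, 3 for each of the 9 combinations of strain (BY4741, LCY001, LCY002) and carbon source (glucose, galactose, ethanol/glycerol). Per the labels' protocols, the cultures were started from individual colonies, grown overnight in medium without histidine and diluted into the 3 carbon sources. The histidine content of those last cultures is not given in the sources used here. RNA was extracted with TRIzol, selected with oligo(dT) beads and primed with random hexamers, per the labels' protocols. Whether the libraries mark the strand is not given in the sources used here, so overlapping and antisense transcripts were treated as uncertain. The deposited values are RSEM expected counts per gene, and per the submitters' processing notes HISAT2 2.1.0, Bowtie2 2.2.5 and RSEM 1.2.8 were used with build R64. These expected counts are estimates that need not be whole, and they were rounded to whole numbers before any test.

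The files hold 5995 genes, of which 5980 IDs matched the reference annotation used for symbols and coordinates and 15 did not. Genes without such a match took at most 0.033% of a library's counts where they were transcripts added by the submitters. Library totals ran from 14484847 to 16219263, and a gene at 0 counts was given the limit of 3 counts. For each of the 27 replicate pairs a chi-square over genes with at least 20 counts gave 3.38 to 20.26 per degree of freedom, so that 0 pairs agreed within sampling noise and 0 held identical values. The plasmid sequence and reads that span it were not analysed here. The mitochondrial genome list could not be measured, since 0 of its 8 genes appear among the genes of the files.

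Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM scaling, filterByExpr, 1 mean per group, all 27 libraries in the fit), which left 5692 genes. Calls were made at a Benjamini-Hochberg adjusted p below 0.05 within each comparison. The common dispersion was 0.00278, a biological coefficient of variation of 0.0527. The comparisons were LCY002 against LCY001 and LCY001 against BY4741 on each carbon source, galactose and ethanol/glycerol against glucose within each strain, and the interaction of the first comparison with the carbon source. Array genes were also tested against a log2 fold change of 1, with adjustment over the 40 genes. Of 29 gene lists, 27 had enough tested members for the set tests, which used camera in limma 3.58.1 on voom values with a preset correlation of 0.01 and again with a correlation estimated from the residuals. After it was seen that this estimate moved with the order of the libraries and design columns, it was computed with 1 fixed order that avoids near-zero terms. Set test p-values were adjusted over the lists of a comparison, and camera tests whether a list stands apart from all other genes. Lists, comparisons, tests and the rule for named genes were fixed before the data were examined.

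Genes were named by that rule. It takes the 4 marker genes; for each array module and carbon source the largest and smallest log2 fold change and up to 5 genes that were not called; the 8 largest rises and falls outside the array per strain comparison; the 10 largest per carbon comparison in BY4741; the 6 largest per interaction; and up to 4 called members per list. Rises and falls had to pass the test, reach a mean of 5 CPM and, except in the interactions, show no overlap between the groups' libraries. A few array genes outside the rule were named after their values were seen, namely those above or below a doubling on all 3 carbon sources. Genes were treated as uncertain where they carry a transcript added by the submitters (131 genes), where they lie within reach of such a transcript (190), where they overlap another annotated gene (164), or where replicates differed by over 3 fold at 5 CPM or more (12), 497 genes in all.

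The tests were also run on simulated counts. In simulated libraries of LCY002 and LCY001 in glucose, edgeR recovered 76% of genes changed by 1.25 fold, 96% by 1.5 fold and 100% by 2 and by 4 fold among 5681 genes, and it called 14 of 5441 unchanged genes. DESeq2 recovered the same shares and called 18 unchanged genes. For the interaction of galactose and glucose the shares were 42%, 94%, 100% and 100%. With the 40 array genes simulated at a doubling, 38 were called higher and 0 were called as differing from a doubling by edgeR. Simulated libraries of LCY001 and BY4741 in glucose without any change gave 0 called genes of 5681 in edgeR. A list of 20 genes shifted in simulated galactose libraries was called by camera with the preset correlation. Genes were drawn independently there, so this does not test camera on lists whose genes vary together.

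Alternatives planned from the start were RLE size factors, total counts as the scale, TMM factors without the 40 array genes, no low-count filter, DESeq2 1.42.0, a fit of only the libraries compared, the replicate number as a block, BY4741 in place of LCY001 as the control for the array genes, and leaving out each library in turn. Added after seeing the data were BY4741 as the control for the gene counts and a test without the uncertain genes. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.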

Results

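Messenger RNA of the yeast Saccharomyces cerevisiae was sequenced in 27 libraries, made from 3 strains grown on 3 carbon sources with 3 replicates in each of the 9 groups. BY4741 is a laboratory strain that lacks working copies of the marker genes HIS3, LEU2, URA3 and MET17. LCY001 is BY4741 with a centromeric plasmid that carries HIS3. LCY002 is BY4741 with a centromeric HIS3 plasmid that also carries an array of 40 genes of galactose use, glycolysis and ergosterol synthesis. The carbon sources were glucose, galactose, and ethanol with glycerol, and the replicates were individual colonies per the labels. Total expected counts ran from 14484847 to 16219263 per library, so that 3 counts in the smallest library equal 0.207 CPM (counts per 1e6 library counts). Counting floors of this kind cover counting error only. Spearman correlations between replicates, across genes, lay between 0.993 and 0.999. The first principal component, which held 59.7% of the variance, placed the libraries by carbon source, with glucose at one end and ethanol/glycerol at the other. Levels are given as mean CPM ± SD (n = 3 libraries per group). For these levels the library sizes were scaled by their TMM factors, while the limit of 0.207 CPM uses the unscaled total. Log2 fold changes are given as the fitted value ± SE, with the SE taken from the F test in the fit of all 27 libraries.

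The marker genes follow the genotypes on the labels. LEU2, URA3 and MET17, which serve leucine, uracil and methionine synthesis, had 0 counts in all 27 libraries, which allows a level of up to 0.207 CPM in the smallest. HIS3, which encodes an enzyme of histidine synthesis (gene ID 854377, build R64, chromosome XV, 721946 to 722608), stood at 37.6 ± 2.15 CPM in BY4741, 1496 ± 26.3 CPM in LCY001 and 507 ± 18.9 CPM in LCY002 in glucose. The his3Δ1 allele of BY4741 removes only part of the gene, so a low HIS3 level there does not go against the label. In galactose the HIS3 levels were 27.9 ± 1.66, 1171 ± 106 and 438 ± 9.67 CPM in the same order. In ethanol/glycerol they were 46.8 ± 2.02, 1052 ± 48.7 and 653 ± 11.1 CPM. HIS3 was therefore lower in LCY002 than in LCY001 on every carbon source, with log2 fold changes of -1.56 in glucose, -1.42 in galactose and -0.69 in ethanol/glycerol (SE 0.05 each).

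LCY002 was first compared with LCY001 for the 40 genes on the array, which asks how far their transcripts rise when the array is added to a strain with the same marker. Reads of the plasmid copy and of the chromosomal copy fall on one gene count and were not separated. The array genes took 8.61% ± 0.04 of all counts in LCY001 and 13.7% ± 0.18 in LCY002 in glucose, 7.72% ± 0.49 and 14.0% ± 0.18 in galactose, and 4.64% ± 0.06 and 8.42% ± 0.31 in ethanol/glycerol. In glucose 36 array genes rose, 3 fell and 1 was not called. In galactose 39 rose and 1 fell, and in ethanol/glycerol 39 rose and 1 was not called. The counts were the same adjusted over the list alone. The median log2 fold change over the 40 genes was 1.08 in glucose, 1.08 in galactose and 1.30 in ethanol/glycerol, with SDs of the replicate medians of 0.028, 0.027 and 0.055. These correspond to 2.12, 2.12 and 2.47 fold. Higher levels on all 3 carbon sources were called for 35 of the 40 genes.

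**Figure D1:**
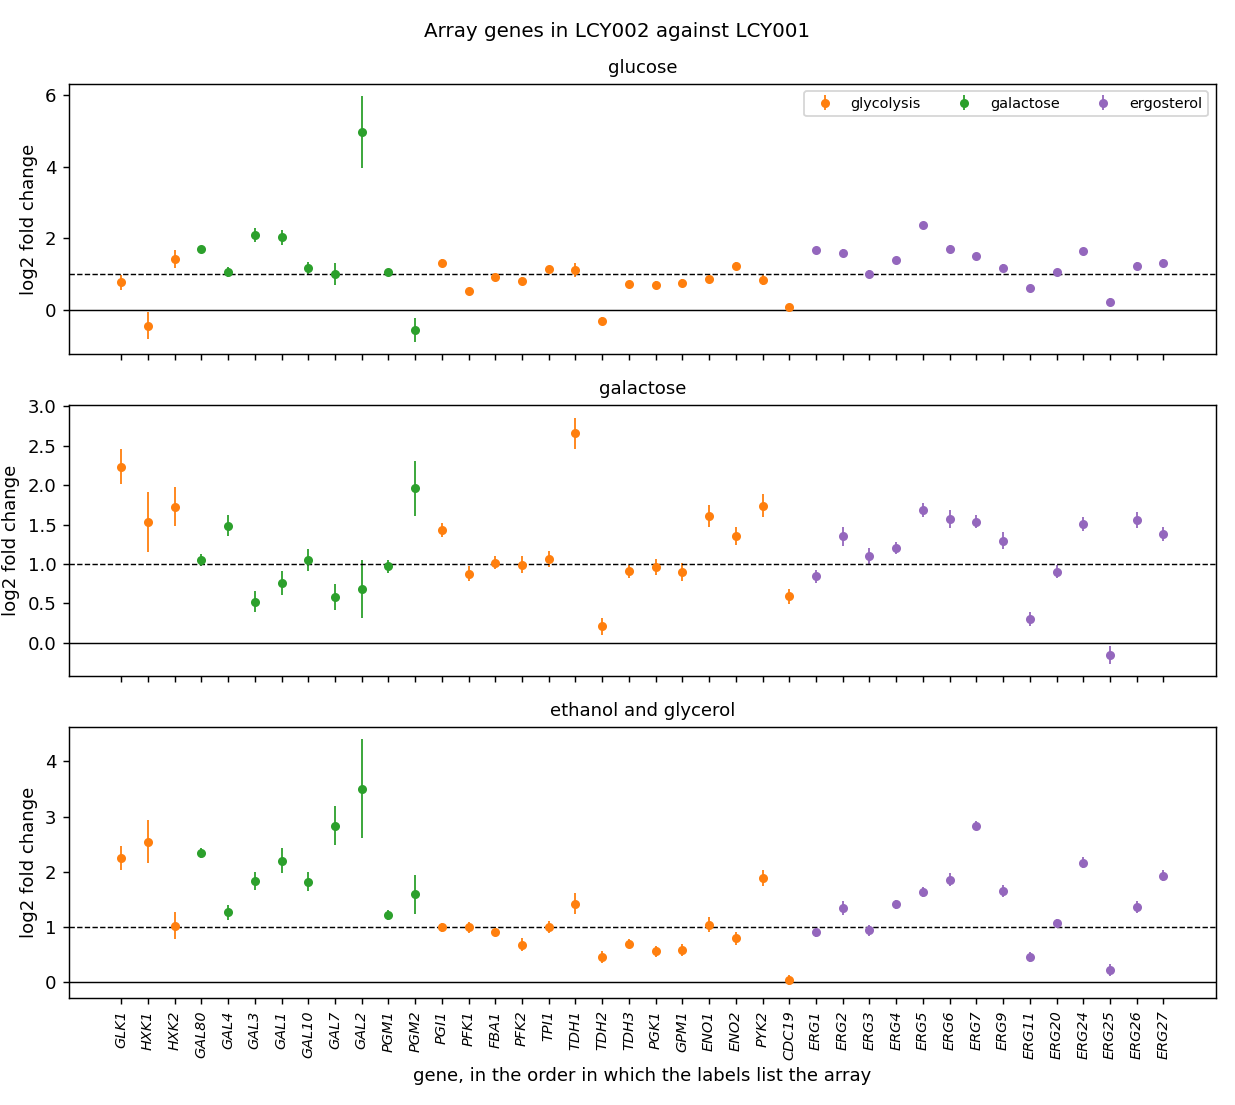
Log2 fold change of each of the 40 array genes in LCY002 against LCY001, for glucose, galactose and ethanol/glycerol. The vertical axis is the log2 fold change, its range differing between panels, and the horizontal axis is the order of the array. Points are fitted values coloured by module. Bars are 95% intervals from the fit of all 27 libraries, with 3 libraries per strain and carbon source. The medians are 1.08, 1.08 and 1.30, and CDC19 lies at 0.08 in glucose and 0.04 in ethanol/glycerol.

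The ergosterol genes of the array had the highest module median in glucose and galactose. All 14 rose in glucose and in ethanol/glycerol, and 13 rose in galactose, with median log2 fold changes of 1.35, 1.39 and 1.32. With BY4741 as the control the medians were 1.26 in glucose, 1.44 in ethanol/glycerol and 1.23 in galactose. In glucose this lay below the 1.67 of the galactose genes with that control. LCY001 itself was lower than BY4741 for 9 of the 14 ergosterol genes in glucose. ERG5, which encodes the sterol C-22 desaturase (gene ID 855029, chromosome XIII, 300869 to 302485), rose from 79.3 ± 0.727 to 407 ± 18.9 CPM in glucose, a log2 fold change of 2.36 ± 0.05. ERG7, the lanosterol synthase gene (gene ID 856470, chromosome VIII, 239098 to 241293), rose from 148 ± 4.22 to 1054 ± 2.11 CPM in ethanol/glycerol. ERG25, the C-4 methyl sterol oxidase gene, changed little, at 0.21 ± 0.05 in glucose and 0.22 ± 0.05 in ethanol/glycerol, and was the array gene that fell in galactose (-0.15 ± 0.05, adjusted p = 0.0318). That call ended without LCY001 replicate 1 (-0.10) or 3 (-0.12), or LCY002 replicate 1 (-0.13), 2 (-0.16) or 3 (-0.16). The 11 sterol synthesis genes that the array does not carry had medians near 0, of -0.01, -0.08 and 0.02, the last turning to -0.03 with total counts as the scale. Among these 11 genes, 1 fell in glucose, 2 rose and 5 fell in galactose, and 2 rose and 3 fell in ethanol/glycerol. Against all other genes the ergosterol module was called higher on each carbon source (camera adjusted p = 0.000457, 0.000193 and 0.000943 with an estimated correlation).

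Galactose genes of the array had higher median rises in glucose and ethanol/glycerol than in galactose. The 9 genes had median log2 fold changes of 1.15 in glucose, 0.97 in galactose and 1.83 in ethanol/glycerol. Against BY4741 these medians were 1.67, 0.45 and 1.79, with 6 of 9 genes called higher in galactose, where LCY001 itself was lower than BY4741 for 7 of the 9 (median -0.32). GAL1, the galactokinase gene (gene ID 852308, chromosome II, 279021 to 280607), rose from 11.8 ± 1.64 to 47.8 ± 1.10 CPM in glucose and from 8791 ± 653 to 14920 ± 291 CPM in galactose. Its log2 fold change was 2.02 ± 0.10 in glucose and 0.76 ± 0.07 in galactose, a difference of -1.26 ± 0.13 (adjusted p = 1.39e-08 for the interaction). GAL3, which encodes the galactose sensor, gave 2.09 ± 0.09 and 0.52 ± 0.07 in the same media. PGM2, the main phosphoglucomutase gene, fell by 0.57 ± 0.16 in glucose and rose by 1.96 ± 0.17 in galactose. Against BY4741 in place of LCY001, PGM2 was 0.96 higher in LCY002 in glucose, so its direction there turns with the control strain. GAL2, the galactose permease gene, had the largest rise in glucose, 4.97 ± 0.48, but it can share reads with a transcript added by the submitters and is uncertain. The module was called higher in galactose and in ethanol/glycerol (camera adjusted p = 0.00416 and 0.0204 with an estimated correlation) and, in glucose, with the preset correlation alone (adjusted p = 3.77e-07, against adjusted p = 0.0585 with an estimated correlation).

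Glycolytic genes of the array had the lowest module median in glucose and ethanol/glycerol. Of the 17, 14 rose and 2 fell in glucose, all 17 rose in galactose and 16 rose in ethanol/glycerol, with medians of 0.80, 1.06 and 0.99. HXK2, the hexokinase gene that is dominant on glucose, rose from 1610 ± 125 to 4309 ± 193 CPM in glucose. TDH1, which encodes the minor glyceraldehyde-3-phosphate dehydrogenase, rose by 2.66 ± 0.09 in galactose. CDC19, the main pyruvate kinase gene (gene ID 851193, chromosome I, 71786 to 73288), stood at 12350 ± 190 CPM in LCY001 and 13030 ± 345 CPM in LCY002 in glucose (log2 fold change 0.08 ± 0.04, adjusted p = 0.149). In ethanol/glycerol its log2 fold change was 0.04 ± 0.04 (adjusted p = 0.512), and in galactose it rose by 0.59 ± 0.04. TDH2, another dehydrogenase gene, fell by 0.32 ± 0.05 in glucose. Reads moved between the TDH genes cannot be told apart from this fall, nor from the size of the TDH1 rise in galactose. HXK1, a second hexokinase gene, changed by -0.45 ± 0.18 in glucose (adjusted p = 0.0384). That call ended without LCY001 replicate 1 (-0.32), LCY002 replicate 1 (-0.42), LCY002 replicate 2 (-0.44) or LCY002 replicate 3 (-0.49), and against BY4741 the gene was 1.30 higher. The module was called higher in galactose and in ethanol/glycerol (camera adjusted p = 0.00217 and 0.0388 with an estimated correlation) and with the preset correlation in glucose (adjusted p = 0.0821 with an estimated correlation).

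A test against a doubling asked which array genes departed from a log2 fold change of 1. A doubling takes it that each cell holds 1 added copy of the gene, expressed like the chromosomal copy. The plasmid copy number was not measured, and HIS3, which both plasmids carry, was lower in LCY002 than in LCY001 on every carbon source. A departure from a doubling therefore cannot be told apart from a copy number other than 1. In glucose 31 genes did, 18 above and 13 below. In galactose there were 19 above and 11 below, and in ethanol/glycerol 22 above and 10 below. The test was not repeated with total counts as the scale or with BY4741 as the control. With total counts the median of the 40 genes was 0.98 in glucose and 0.95 in galactose, and against BY4741 it was 1.24 and 0.99. In glucose LCY001 itself was higher than BY4741 for 13 array genes and lower for 11. The calls near a doubling may therefore depend on scale and control. On all 3 carbon sources 9 genes lay above a doubling: ERG2, ERG4, ERG5, ERG6, ERG7, ERG9, ERG24, ERG26 and ERG27. A further 5 lay below it on all 3: the glycolytic genes TDH2, TDH3 and CDC19 and the sterol genes ERG11 and ERG25. For TDH2 and TDH3 this holds for the counts as assigned, since reads may have moved between the TDH genes. In galactose the summed level of TDH1, TDH2 and TDH3 rose by 0.97. The rise itself differed between galactose and glucose for 26 array genes and between ethanol/glycerol and glucose for 23. All 11 glycolytic genes in the first of these sets rose more in galactose when LCY001 was the control. Against BY4741 the glycolytic medians were 0.99 in glucose, 1 in galactose and 0.96 in ethanol/glycerol, so they hardly moved with the carbon source. LCY001 itself was higher than BY4741 for 7 of the 17 glycolytic genes in glucose and lower for 5 in galactose.

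Outside the array, glucose-grown LCY002 had lower levels of reserve carbohydrate and stress genes than LCY001, and higher levels of amino acid synthesis genes. Of the 24 genes of the stress and reserve carbohydrate list, 22 fell and 2 rose, with a median log2 fold change of -1.32 and the same counts adjusted over the list alone. GLC3, the glycogen branching enzyme gene, fell from 533 ± 53.1 to 99.3 ± 7.25 CPM (log2 fold change -2.42 ± 0.17). GSY1, which encodes glycogen synthase, changed by -2.38 ± 0.15 and CTT1, the cytosolic catalase gene, by -2.13 ± 0.18. The list was called lower with the preset correlation (camera adjusted p = 1.51e-13) and not with an estimated one (adjusted p = 0.0952 with an estimated correlation). With BY4741 as the control its median in glucose was only -0.35. All 28 genes of the amino acid synthesis list rose, with a median of 0.53 (adjusted p = 0.0119 with an estimated correlation). ARG1, the argininosuccinate synthetase gene, went from 551 ± 6.40 to 1445 ± 21.1 CPM and LYS1, of lysine synthesis, rose by 1.32 ± 0.05. Of the 6 histidine synthesis genes 5 rose, HIS5 by 0.88 ± 0.05 (adjusted p = 0.0921 with an estimated correlation).

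Respiratory genes were lower in the same comparison and ribosome biogenesis genes higher. Of 14 tricarboxylic acid cycle genes 11 fell and of 30 respiratory chain and ATP synthase genes 25 fell, with medians of -0.35 and -0.27. SDH1, a succinate dehydrogenase subunit gene, fell from 96.0 ± 8.75 to 48.1 ± 0.617 CPM and CIT1, the mitochondrial citrate synthase gene, changed by -0.95 ± 0.11. Both lists lost their call with an estimated correlation (adjusted p = 0.198 and adjusted p = 0.165 with an estimated correlation). Of the 20 ribosome biogenesis genes 19 rose, with a median of 0.29 (adjusted p = 0.392 with an estimated correlation). NSR1, a nucleolar protein gene, was 0.56 ± 0.09 higher. All 20 of these genes were lower in LCY001 than in BY4741 in glucose, so their rise is shown against LCY001 only. Among single genes outside the array, the cell wall gene PIR5 (1.83 ± 0.12), the thiazole synthesis gene THI4 (1.67 ± 0.14) and the ribonucleotide reductase gene RNR3 (1.59 ± 0.10) were among the largest rises. In total 3058 of 5692 genes differed, 1620 higher and 1438 lower, of which 83 and 108 by at least 2 fold. The 3 libraries of each strain did not overlap for 60.7% of genes, against 10% by chance. Of the 3058 genes, 1113 were also called in the same direction with BY4741 in place of LCY001.

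In galactose the stress genes stood the other way round. Of the same 24 genes 21 rose in LCY002 against LCY001 and 3 were not called, while 21 rose and 1 fell adjusted over the list alone. Of the list, HSP26, a small heat shock protein gene, rose by 2.63 ± 0.20. HSP30, a plasma membrane heat shock protein gene that is not on the list, rose from 57.4 ± 30.6 to 518 ± 81.2 CPM (log2 fold change 3.17 ± 0.23). HSP104, the disaggregase gene, rose by 1.56 ± 0.09 and CTT1 by 1.51 ± 0.18. The list median was 0.89 (adjusted p = 0.08 with an estimated correlation). With BY4741 as the control it was -0.09, so the rise is shown against LCY001 only. All 28 amino acid synthesis genes rose here too, with a median of 0.64 (adjusted p = 0.00205 with an estimated correlation). ARG1 rose by 1.81 ± 0.04 and LYS20, a homocitrate synthase gene, by 1.66 ± 0.05. Histidine synthesis genes rose in 5 of 6 cases (adjusted p = 0.0219 with an estimated correlation), HIS4 by 1.36 ± 0.06.

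Iron uptake genes fell in galactose, with 11 of 14 lower and a median of -0.59 (adjusted p = 0.197 with an estimated correlation). Most of these 14 genes were higher in LCY001 than in BY4741 in galactose, so their fall is shown against LCY001 only. FTR1, the high-affinity iron permease gene, fell from 769 ± 32.9 to 363 ± 38.9 CPM, and ARN1, a siderophore transporter gene, changed by -0.78 ± 0.12. Fermentation genes outside the array rose in 6 of 8 cases (adjusted p = 0.0464 with an estimated correlation), with PDC6, a pyruvate decarboxylase isozyme gene, 0.84 ± 0.21 higher. Tricarboxylic acid cycle genes fell in 10 of 14 cases, 11 adjusted over the list alone, and respiratory chain genes in 21 of 30, 22 adjusted over the list alone. Their medians were -0.21 and -0.25 (adjusted p = 0.394 and adjusted p = 0.153 with an estimated correlation). FUM1, the fumarase gene, changed by -0.38 ± 0.04. The count of genes that differed was 2175, 1147 higher and 1028 lower, with 46.7% of genes not overlapping against 10% by chance. Of these, 1040 were also called in the same direction with BY4741 in place of LCY001.

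In ethanol/glycerol, genes for making glucose from the carbon source rose in LCY002 and genes for making ribosomes fell. All 13 gluconeogenesis and glyoxylate cycle genes rose, with a median of 0.58 (adjusted p = 0.0855 with an estimated correlation). PCK1, which encodes phosphoenolpyruvate carboxykinase, went from 1789 ± 19.1 to 3113 ± 125 CPM, and MDH2, the cytosolic malate dehydrogenase gene, rose by 1.18 ± 0.10. All 20 ribosome biogenesis genes fell, with a median of -0.43 (adjusted p = 0.284 with an estimated correlation), and 95 of 134 cytosolic ribosomal protein genes fell, 96 adjusted over the list alone (median -0.21, adjusted p = 0.436 with an estimated correlation). RPA135, an RNA polymerase I subunit gene, changed by -0.67 ± 0.06. Iron uptake genes rose in 10 of 14 cases (median 0.71, adjusted p = 0.284 with an estimated correlation), with FIT2, a cell wall mannoprotein gene of siderophore retention, 2.64 ± 0.16 higher and FIT3 1.46 ± 0.12 higher. Amino acid synthesis genes rose in 16 of 28 cases and fell in 3, and 9 were not called (median 0.14, adjusted p = 0.358 with an estimated correlation). Stress genes rose in 16 of 24 cases and fell in 2 (median 0.38, adjusted p = 0.449 with an estimated correlation). The largest single rises outside the array were in SPG1 (2.91 ± 0.12), a gene needed in stationary phase, and RGI2 (2.89 ± 0.14), a gene of energy metabolism. Among the falls were MCD1, a cohesin subunit gene, at -1.06 ± 0.05, and YOX1, a cell cycle repressor gene, at -1.03 ± 0.09. In total 3406 genes differed, 1674 higher and 1732 lower, and 66.1% of genes did not overlap against 10% by chance.

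**Figure D2:**
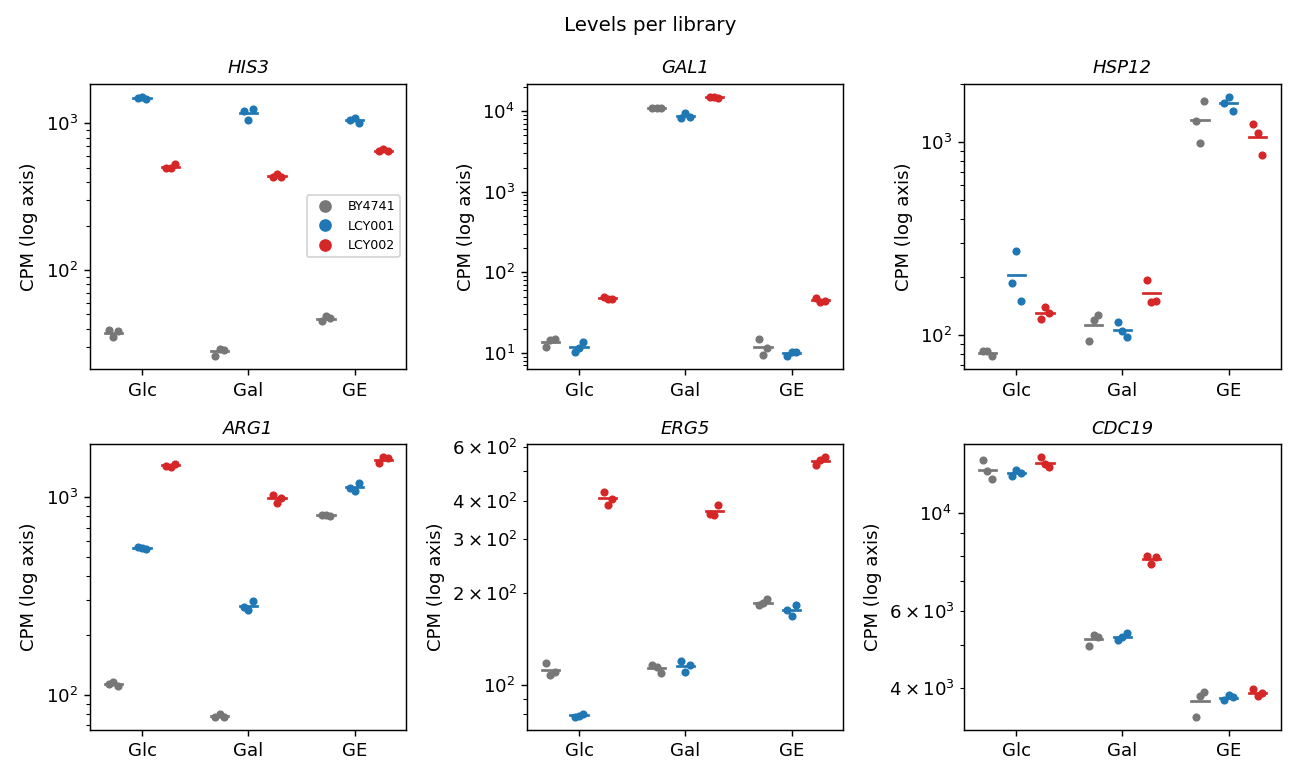
Level in CPM (vertical axis, log scale) of HIS3, GAL1, HSP12, ARG1, ERG5 and CDC19 in each of the 27 libraries, by strain and carbon source (horizontal axis); each point is 1 library and each line the mean of 3. HIS3 lies at 37.6 CPM in BY4741, 1496 in LCY001 and 507 in LCY002 in glucose, and GAL1 goes from 11.8 CPM in LCY001 in glucose to 8791 in galactose.

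The difference between LCY002 and LCY001 was then tested for a change with the carbon source. Between galactose and glucose it changed for 2696 genes, 1340 upward and 1356 downward. Reserve carbohydrate and stress genes led this set, with 22 of 24 upward and a median of 2.46 (adjusted p = 0.168 with an estimated correlation). LCY001 itself differed from BY4741 for this list, with medians of 1.09 in glucose and -0.89 in galactose. Against BY4741 the LCY002 medians were -0.35 and -0.09, so the change is shown against LCY001 only. The interactions were not run with BY4741 as the control. Within the stress list GLC3 had an interaction of 3.70 ± 0.24. Outside that list HSP30 had one of 4.17 ± 0.31 and PCL1, a G1 cyclin gene, one of -2.13 ± 0.14. Between ethanol/glycerol and glucose it changed for 3443 genes, 1611 upward and 1832 downward. There SPG1 had an interaction of 4.7 ± 0.34 and CYC7, a cytochrome c isoform gene, one of 3.60 ± 0.22, while amino acid synthesis genes moved downward in 25 of 28 cases with a median of -0.43 (adjusted p = 0.351 with an estimated correlation).

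LCY001 was next compared with BY4741, from which it differs by the HIS3 plasmid without the array. Per the labels all strains were first grown in medium without histidine, although BY4741 without a plasmid needs it, and whether BY4741 was given histidine is not stated. The plasmid and the histidine supply are therefore not separated, above all for histidine and amino acid synthesis genes. It shares its LCY001 libraries with the comparison of LCY002 and LCY001, so that the chance values of those libraries enter both with opposite signs. In glucose 3153 genes differed, 1571 higher and 1582 lower. Amino acid synthesis genes rose in 23 of 28 cases and fell in 2 (median 0.37, adjusted p = 0.111 with an estimated correlation). ARG1 rose from 113 ± 3.17 to 551 ± 6.40 CPM. SNZ1, a vitamin B6 synthesis gene, was 3.37 ± 0.14 higher and ARO9, of aromatic amino acid breakdown, 3.12 ± 0.11 higher. Stress genes rose in 22 of 24 cases (median 1.09, adjusted p = 0.161 with an estimated correlation), GSY1 by 1.60 ± 0.14, while 1 fell adjusted over the list alone. Ribosomal protein genes fell in 116 of 134 cases, 119 adjusted over the list alone, and ribosome biogenesis genes in 20 of 20 (medians -0.30 and -0.42, adjusted p = 0.263 and adjusted p = 0.252 with an estimated correlation). IMD2, an IMP dehydrogenase gene of guanine nucleotide synthesis, had the largest fall, -2.41 ± 0.08. PHO84, the high-affinity phosphate transporter gene, changed by -0.91 ± 0.08 and was 1 of 9 phosphate genes of 12 that fell (adjusted p = 0.0834 with an estimated correlation).

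In galactose 2215 genes differed between LCY001 and BY4741, 1178 higher and 1037 lower. Histidine synthesis genes rose in 5 of 6 cases, HIS1 by 1.27 ± 0.05, and amino acid synthesis genes in 23 of 28 (adjusted p = 0.0334 for each with an estimated correlation). Adjusted over the list alone, 24 of these 28 rose and 2 fell. Stress genes fell in 19 of 24 cases, 20 adjusted over the list alone, with a median of -0.89 (adjusted p = 0.096 with an estimated correlation). TSL1, a trehalose synthase subunit gene, changed by -1.84 ± 0.11. HSP30, which is not on the stress list, changed by -2.79 ± 0.23. Iron uptake genes rose in 12 of 14 cases, 13 adjusted over the list alone (median 0.80, adjusted p = 0.117 with an estimated correlation).

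Ethanol/glycerol gave the smallest difference between LCY001 and BY4741, 657 genes with 377 higher and 280 lower. This count depends on the libraries in the fit, with 257 genes when only the 6 libraries compared were used. Leaving out single libraries gave 404, 394 and 1030 genes without BY4741 replicates 1, 2 and 3, and 403 and 426 without LCY001 replicates 1 and 3. Among single genes, BIO3, BIO4 and BIO2, the biotin synthesis genes, rose by 3.52 ± 0.26, 3.29 ± 0.24 and 3.07 ± 0.16, and VHT1, the biotin transporter gene, rose from 94.7 ± 3.72 to 508 ± 25.8 CPM. HIS4 rose by 1.99 ± 0.06, and histidine synthesis genes rose in 4 of 6 cases (adjusted p = 0.00951 with an estimated correlation). Amino acid synthesis genes rose in 21 of 28 cases, 25 adjusted over the list alone, with a median of 0.19 (adjusted p = 0.00951 with an estimated correlation). ADE17, a purine synthesis gene that takes up a by-product of histidine synthesis, was 2.55 ± 0.12 higher.

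**Figure D3:**
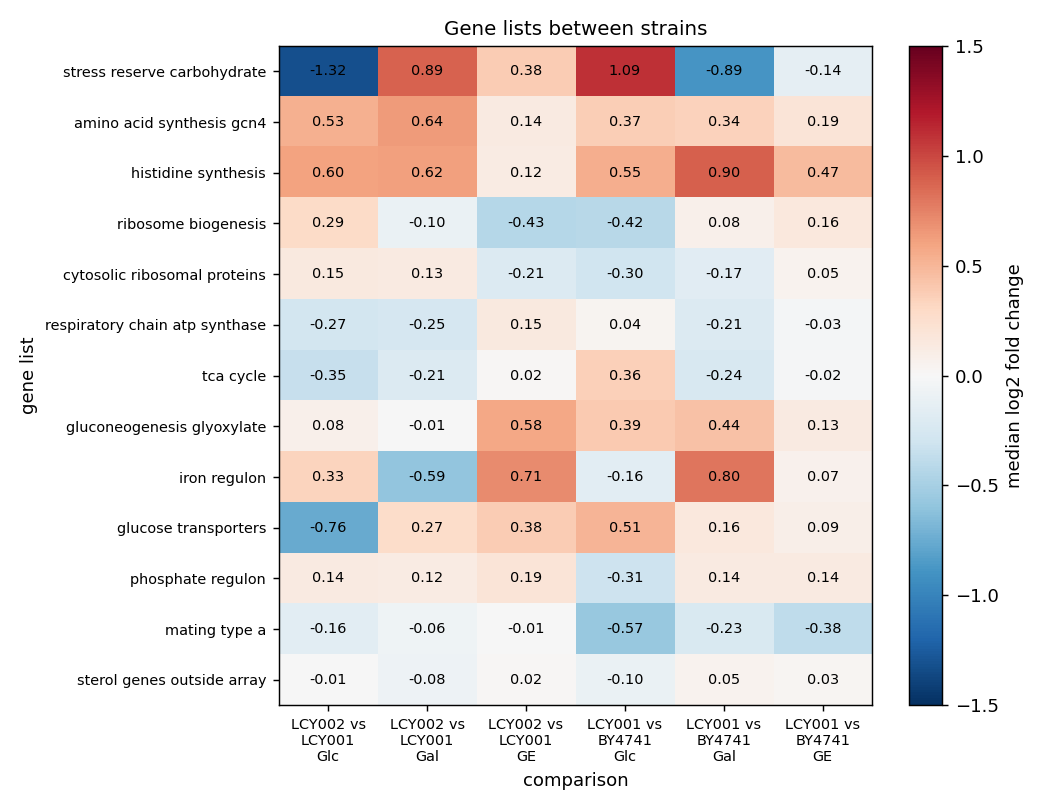
Median log2 fold change of 13 gene lists (vertical axis) in the 6 strain comparisons (horizontal axis), shown as colour and as the printed number; each median is over the tested genes of the list, from 3 libraries per strain and carbon source. The stress and reserve carbohydrate list reads -1.32 in glucose and 0.89 in galactose for LCY002 against LCY001, and 1.09 and -0.89 for LCY001 against BY4741.

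Carbon sources were compared within each strain to describe the growth states themselves, and BY4741 is given in detail. From glucose to galactose the Leloir pathway genes rose steeply, with GAL7 at 11.15 ± 0.14 and GAL10 at 9.11 ± 0.10, while GAL1 went from 13.7 ± 1.52 to 10960 ± 138 CPM. The 5 targets of the activator Gal4 that are outside the array all rose, the uracil permease gene FUR4 by 1.81 ± 0.09 (list adjusted p = 0.0344 with an estimated correlation). All 30 respiratory chain genes and all 14 tricarboxylic acid cycle genes rose, with medians of 1.75 and 1.61 (adjusted p = 0.0344 and adjusted p = 0.0523 with an estimated correlation). CYC1, the main cytochrome c gene, rose by 2.38 ± 0.07. The glucose-induced hexose transporter genes HXT1 and HXT4 fell, by 5.48 ± 0.08 and 5.10 ± 0.23, and so did MIG2, a glucose-responsive repressor gene, by 4.02 ± 0.13. Ribosomal protein genes fell in 128 of 134 cases, 129 adjusted over the list alone (median -0.50, adjusted p = 0.18 with an estimated correlation). In total 3730 genes differed in BY4741, 3378 in LCY001 and 3421 in LCY002, and in BY4741 71.1% of genes did not overlap against 10% by chance.

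From glucose to ethanol/glycerol the list of glyoxylate cycle and gluconeogenesis genes had the highest median of the 27 lists tested. All 13 rose in BY4741, with a median of 5.62 (adjusted p = 0.117 with an estimated correlation). The malate synthase gene MLS1 rose by 7.97 ± 0.10, PCK1 by 7.80 ± 0.10, and ICL1, the isocitrate lyase gene, from 32.3 ± 3.67 to 2442 ± 253 CPM. All 8 genes of glycerol and ethanol use rose, including the lactate permease gene JEN1 by 5.69 ± 0.09 and the glycerol symporter gene STL1 by 5.37 ± 0.15 (median 3.66, adjusted p = 0.117 with an estimated correlation). Tricarboxylic acid cycle genes rose in 14 of 14 cases and respiratory chain genes in 29 of 30 (medians 2.88 and 2.46, adjusted p = 0.118 and adjusted p = 0.117 with an estimated correlation). Ribosomal protein genes fell in 131 of 134 cases and 1 rose (median -0.94, adjusted p = 0.22 with an estimated correlation), and all 20 ribosome biogenesis genes fell, GAR1 by 1.39 ± 0.06 (adjusted p = 0.313 with an estimated correlation). HXT1 fell by 5.93 ± 0.08, and PDC1, the main pyruvate decarboxylase gene, went from 13490 ± 1192 to 3127 ± 352 CPM. The counts were 4633 genes in BY4741, 4445 in LCY001 and 4756 in LCY002, with 82.2% of genes not overlapping in BY4741 against 10% by chance.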

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

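All tests of the patterns weighed here were chosen only after the result was seen, as were the tests of other splits of the libraries for LCY002 against LCY001 in glucose and for the interaction of galactose and glucose, while the other tests of splits were set beforehand. The results in this part drew attention because the difference between LCY002 and LCY001 itself differed between carbon sources by an interaction test in edgeR.

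Between galactose and glucose the difference changed for 2696 genes, among them 26 of the 40 array genes. The named genes with the largest positive interactions (log2, galactose minus glucose) were HXT6 at 6.29, RGI1 at 4.46, HSP30 at 4.17, EGO4 at 3.97, CYC7 at 3.76 and GLC3 at 3.70. Those with the most negative ones were KRE6 at -5.96, GAL2 at -4.28, TIS11 at -2.53, PCL1 at -2.13, SIT1 at -2.06 and PRM7 at -2.03. HXT6, RGI1, KRE6, TIS11 and SIT1 differed over 3 fold between replicates, and GAL2 can share reads, so that these 6 are uncertain. Without LCY001 replicate 2 in galactose the values of HXT6, RGI1 and EGO4 became 7.05, 5.41 and 4.61. The call of KRE6 ended without replicate 1 (-5.39), 2 (-10.43) or 3 (-5.42) of LCY001 in glucose and without LCY002 replicate 1 in glucose (-4.38). Lists called with the preset correlation had interaction medians of 0.31 for the glycolytic array genes, 1.03 for hexose transporters, 2.46 for stress and reserve carbohydrate genes, -1.14 for iron uptake genes and -0.37 for ribosome biogenesis genes. With an estimated correlation camera called 0 of 27 lists here, with 3 at an unadjusted p below 0.05 and 5 called with the preset correlation.

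Between ethanol/glycerol and glucose the difference changed for 3443 genes, among them 23 array genes. The largest positive interactions among named genes were HXT6 at 6.31, RGI2 at 5.19, SPG1 at 4.7, COX26 at 4.11, TPS1 at 3.75 and CYC7 at 3.60. The most negative were KRE6 at -5.34, YOX1 at -2.02, BMT6 at -1.86, AQR1 at -1.86, RSA4 at -1.84 and ARO9 at -1.83. HXT6, TPS1 and KRE6 differed over 3 fold between replicates and are uncertain. TPS1 lost its call without LCY001 replicate 1 (3.55) or 3 (3.39) in ethanol/glycerol, LCY001 replicate 3 in glucose (3.03), LCY002 replicate 3 in ethanol/glycerol (3.42), or LCY002 replicate 1 (3.79) or 3 (3.40) in glucose, and its value was 4.59 without LCY001 replicate 2 in ethanol/glycerol. KRE6 lost its call without LCY001 replicate 3 (-5.27) or LCY002 replicate 3 (-5.18) in ethanol/glycerol, LCY001 replicate 1 (-4.77), 2 (-9.82) or 3 (-4.80) in glucose, or LCY002 replicate 1 in glucose (-3.76). Higher list medians were found for galactose array genes (0.22), hexose transporters (0.91), tricarboxylic acid cycle genes (0.35), respiratory chain genes (0.43), gluconeogenesis genes (0.65), glycerol and ethanol use genes (0.86) and stress genes (1.71). Lower medians were found for histidine synthesis (-0.40), amino acid synthesis (-0.43), sulfur and methionine (-0.42), ribosome biogenesis (-0.73) and cytosolic ribosomal protein genes (-0.36). Camera with an estimated correlation called 0 of 27 lists, with 3 at an unadjusted p below 0.05 and 12 called with the preset correlation. In 100 drawn splits of the libraries the real and the highest other count were 2696 and 2242, and 3443 and 2371. These splits exchange the strains and so remove the strain difference itself, which makes them no test of an interaction.

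The first pattern weighed is that stress and reserve carbohydrate genes were lower in LCY002 than in LCY001 in glucose and higher in galactose. A single library is argued against, since the list median stayed at -1.28 or beyond in glucose and at 0.81 or above in galactose with any 1 library left out. Shared reads and scaling are argued against too, with medians of -1.39 and 1.06 without the genes that can share reads and of -1.43 and 0.75 with total counts as the scale. Against BY4741 the LCY002 medians were only -0.35 in glucose and -0.09 in galactose, so a candidate explanation that stays open is a state of the LCY001 cultures apart from the array. An effect of the array itself also stays open, since the design has 1 strain of each kind.

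The second pattern is that TDH2, TDH3, CDC19, ERG11 and ERG25 lay below a doubling on all 3 carbon sources. The summed level of TDH1, TDH2 and TDH3 rose by 0.62 in glucose and 0.79 in ethanol/glycerol. Reads moved among these near-identical genes therefore do not explain why the 3 together stayed below a doubling there. Which of the 3 lies below it cannot be told, since a sum does not see reads moved between them. In galactose, where the sum rose by 0.97, moved reads stay possible for the whole shortfall. Reads moved between CDC19 and PYK2 are argued against, with summed rises of 0.08 in glucose, 0.61 in galactose and 0.10 in ethanol/glycerol. A fall common to all sterol synthesis genes is argued against, since those outside the array had medians of -0.01, -0.08 and 0.02. The SDs over these genes were 0.12, 0.17 and 0.19. Their list holds none of the array's ERG genes, so it does not decide a fall limited to the chromosomal copies of those. Weaker transcription of these array copies, or lower output of the chromosomal copies, may remain, and neither was tested because the counts do not separate the copies. The plasmid copy number per cell, which a doubling takes as 1, was not measured either.

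The third pattern is that amino acid synthesis genes were higher in LCY002 than in LCY001 in glucose and galactose. One library is argued against by a smallest list median of 0.51 with any library left out. A state of the LCY001 cultures cannot be told apart from the array. The medians of 1.04 in glucose and 0.95 in galactose for LCY002 against BY4741 do not decide it, because the histidine supply of BY4741 is not stated and these genes depend on it. The lower HIS3 level of LCY002 also cannot be told apart from the array, because both differ between the same strains and the histidine of the cultures is not stated. The interaction median of -0.43 goes with the smaller HIS3 difference in ethanol/glycerol, but LCY001 had more HIS3 than BY4741 and higher levels of these genes as well.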

How the results depend on the processing

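Among the tests in this part, BY4741 as the control for the gene counts and the test without uncertain genes were chosen only after the result was seen. Of 1152 pairs of a named gene and a comparison, DESeq2 left 1142 on their side of the threshold and ended 10 calls, RLE factors ended 2, the absence of a low-count filter 3 and the fit of only the libraries compared 68. With each library left out in turn, and each gene counted once per library, 355 calls ended and 7835 values stayed on their side. With BY4741 as the control, 113 values of array genes stayed on their side of the threshold, uncalled ones included, 4 calls were lost and 3 turned direction: HXK1 to 1.30 and PGM2 to 0.96 in glucose, and GAL2 to -0.08 in galactose, where its call ended. With that control the counts of all genes were 2184 in glucose, 2154 in galactose and 3397 in ethanol/glycerol, of which only 1113, 1040 and 2842 were also called in the same direction against LCY001 (of 3058, 2175 and 3406), so that most calls in glucose and galactose depend on the control strain. The median of the array genes in glucose moved from 1.08 to 0.98 with total counts and to 1.24 against BY4741, and in galactose from 1.08 to 0.95 and 0.99. Total counts moved the median of all genes by over 0.1 in 7 of 14 comparisons, from -0.137 to 0.189. The 657 genes of LCY001 against BY4741 in ethanol/glycerol became 257 with only the libraries compared. For the counts whose change is given here the cause was not tested.

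Strain comparisons are given as LCY002 against LCY001 and then LCY001 against BY4741, each in glucose, galactose and ethanol/glycerol. Without the uncertain genes these comparisons had 2873, 2027, 3167, 2941, 2091 and 615 calls. Leaving out 1 library gave 2659 to 2856, 1736 to 2163 and 3002 to 3287 genes, and then 2763 to 2999, 1746 to 2220 and 394 to 1030. For galactose against glucose it gave 3464 to 3560 in BY4741, 3031 to 3239 in LCY001 and 3099 to 3252 in LCY002. For ethanol/glycerol against glucose it gave 4477 to 4543, 4277 to 4357 and 4628 to 4642. The interactions ranged from 2438 to 2782 and from 3243 to 3430. Array medians ranged from 1.07 to 1.11, 1.07 to 1.15 and 1.27 to 1.33, array genes called higher stayed at 36, 39 and 39, and array genes differing from a doubling ranged from 28 to 31, 27 to 31 and 31 to 32.

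With an estimated correlation camera called 2 lists in place of 14, 6 of 12 and 3 of 14 for LCY002 against LCY001, and 0 of 12 (6 at an unadjusted p below 0.05), 3 of 14 and 3 of 11 for LCY001 against BY4741. For galactose against glucose it called 4 of 18, 4 of 16 and 3 of 18 in BY4741, LCY001 and LCY002. For ethanol/glycerol it called 0 of 14, 0 of 13 and 0 of 13, with 6, 7 and 7 lists at an unadjusted p below 0.05, and for the interactions 0 of 5 and 0 of 12 with 3 and 3. The estimated correlations widen the test by its construction. Same-numbered replicates did not deviate together on average (mean r -0.0212 over 108 pairs, from -0.306 to 0.247, with 7 pairs over 0.1). The mean of 0.0105 for other pairs is no separate check, since deviations within a group sum to 0 and tie it to the first mean. The mean over same-numbered pairs thus gave no sign that the numbers pair the libraries. With the replicate number as a block the strain comparisons called 3015, 2154, 3378, 3118, 2173 and 623 genes, 9 calls among the 1152 pairs were lost, and the array medians stayed at 1.08, 1.08 and 1.30.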

Other observations

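Tests of other splits in this part were set beforehand, except those for LCY002 against LCY001 in glucose, which were chosen only after the result was seen. In ethanol/glycerol, 7 of 12 genes of the phosphate regulon rose in LCY002 against LCY001 and 5 were not called (median 0.19, adjusted p = 0.0842 with an estimated correlation), with PHO84, the high-affinity transporter gene, going from 69.4 ± 1.12 to 141 ± 10.4 CPM and PHO89, the sodium-coupled transporter gene, rising by 2.29 ± 0.15. ENA1, a sodium pump gene, rose by 1.84 ± 0.19 in the same comparison. The a-specific mating genes fell in LCY001 against BY4741 in ethanol/glycerol in 4 of 5 cases (median -0.38, adjusted p = 0.0187 with an estimated correlation), among them AGA2 at -0.62 ± 0.07 and the pheromone receptor gene STE2 at -0.47 ± 0.05. From glucose to ethanol/glycerol in BY4741 all 5 fell, STE2 by 2.09 ± 0.05 (median -1.51, adjusted p = 0.118 with an estimated correlation).

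Unfolded protein response genes were lower in LCY001 than in BY4741 in galactose. Of 11 genes 5 fell and 6 were not called, while 8 fell adjusted over the list alone, with a median of -0.14 (adjusted p = 0.0334 with an estimated correlation), and KAR2, the chaperone gene of the endoplasmic reticulum, changed by -0.44 ± 0.04. Genes of sterol uptake and hypoxia rose in LCY002 against LCY001 in ethanol/glycerol in 8 of 12 cases (median 0.51, adjusted p = 0.155 with an estimated correlation), among them TIR2, a cell wall mannoprotein gene, by 0.88 ± 0.11. Meiosis genes rose in 8 of 11 cases there (median 0.45, adjusted p = 0.0855 with an estimated correlation), with the kinase gene IME2 going from 13.2 ± 1.73 to 26.4 ± 4.28 CPM. Sulfur and methionine genes rose in 14 of 18 cases in LCY002 against LCY001 in glucose (median 0.43, adjusted p = 0.144 with an estimated correlation), MET16 by 0.84 ± 0.07.

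Splits of 3 against 3 libraries number 10 per comparison, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave a count as large. Every other split mixes the groups compared, which shrinks their difference and widens the spread within each. Where the groups differ, low counts in those splits follow from this mixing and are no measure of false calls. For LCY002 against LCY001 the real count and the highest other were 3058 and 1 in glucose, 2175 and 10 in galactose, and 3406 and 0 in ethanol/glycerol. The array genes called higher were 36, 39 and 39 against 0 each. Array genes differing from a doubling were 31 against 26, 30 against 22 and 32 against 19, but splits that mix the strains bring the log2 fold change near 0 by design, so these counts test nothing about a doubling. For LCY001 against BY4741 the counts were 3153 and 0, 2215 and 0, and 657 and 353. For galactose against glucose they were 3730 and 0 in BY4741, 3378 and 3 in LCY001, and 3421 and 0 in LCY002, and for ethanol/glycerol against glucose 4633 and 0, 4445 and 1, and 4756 and 0.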
